A study of Homo sapiens with 12 samples.

How the data were processed

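SHAPE-MaP was applied to 6 in vitro folded SERPINA1 transcripts, with 2 libraries each, 12 in all. Samples were grouped by the transcript variant that the labels give, and the replicate number came from the sample titles. Per the labels' protocols, RNA was folded at 37 °C and treated with 1M7 in DMSO, and libraries were made with the Nextera kit. One table per library was used, with a line for each nucleotide of the transcript.

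Per the file headers, each table gives a depth and a mutation rate in an untreated (background), a 1M7-treated and a denatured channel, the background-subtracted rate divided by the denatured rate, a filtered reactivity and a normalized reactivity. The deposited depths are coverage, the whole number of reads over each nucleotide, with no normalization. The deposited mutation rates are a fraction, mutations divided by depth. Per the file headers, the normalized reactivity and its standard error are a score with no fixed range, which can fall below 0 after background subtraction. From the values, the normalized reactivity equals the filtered reactivity times one factor per library, and nucleotides with an untreated rate of 5% or more carry no reactivity. Reads were aligned with Bowtie2, per the submitters' processing notes, which give no version. Other upstream tools and settings are not given in the sources used here. Because the score is divided by a denatured rate and scaled by the authors, a level can be compared between libraries only after a common scaling, and a nucleotide filtered for high background cannot be analysed.

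The choices below were made before the data were examined, except where an addition is named. The nucleotides from 4 nt before the start codon to the stop codon, 1261 nt, were identical in the 6 transcripts, and the 1247 of them measured in every library formed the shared sequence; 14 were left out. Transcripts were aligned by their own deposited sequences, and positions are transcript positions; a genome was not used here. Each library was multiplied by one factor, between 0.953 and 1.03, so that the mean of its reactivities from the 90th to the 98th percentile of the shared sequence was equal in all libraries. Negative reactivities, 5.23% to 23.1% of a library, were set to 0. Between 6 and 19 nucleotides of a library carried no reactivity.

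Nucleotides were tested with limma 3.58.1 in R 4.3.3, by a moderated F test over the transcripts on log2(reactivity + 0.1) with Benjamini-Hochberg adjustment and a threshold of 0.05. The script was tested on simulated data with the measured means and spreads and 200 changed nucleotides, where it recovered 13.1% of those changed by 1 on the log2 scale and 55.1% of those changed by 2, with 4.31% of its calls false. Values per library were compared between transcripts by the F ratio over all 10395 ways to pair the 12 libraries, so the smallest exact permutation p is 9.62e-05. Differences within a library were averaged per transcript and tested by a two-sided exact sign-flip permutation over 6 transcripts, whose smallest p is 0.03125. The transcripts share the coding sequence and parts of their 5′ UTRs, so the 6 are not fully independent units. Codon positions were tested by 100000 random permutations within codons, whose smallest p is 1e-05. The p-values of the 8 such tests fixed in advance were adjusted together. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

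Folding used the partition function of ViennaRNA 2.7.2, with reactivities added as pseudo-energies (slope 1.8, intercept −0.6 kcal/mol) and pairs spanning at most 600 nt. The named regions and nucleotides followed a rule fixed in advance. It took the 5′ UTR, coding sequence, start codon window, upstream AUG windows, signal peptide and reactive centre loop. It also took the 10 called shared nucleotides with the largest range and the 5 windows with the most called nucleotides, which stayed empty because none was called, and the 5 most and 5 least reactive 25-nt windows of the coding sequence. The measured sequences ended at the stop codon, so a 3′ UTR was not analysed here.

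Alternatives fixed in advance changed the scaling, the floor on negative values, the depth minimum (1000 reads in every channel), the transcript ends, the pseudocount, the threshold, window sizes, the summary, the folding parameters and the replicate number as a block, and each library was left out in turn. Added after the data were examined were the tests per nucleotide in the leader, middle and proximal segments, the ratio of spread between and within transcripts, the fits without the 3 libraries of higher untreated rate or with that class as a block, the transcript differences in derived values with their alternatives and the place of nucleotides at unadjusted p under 0.05. The class was split in the middle of the widest gap between the median untreated rates, at 0.222%. The higher class holds 1 library each of variants 1, 2 and 3, too few for tests within it, so comparisons between transcripts are given within the lower class only.

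Replicate numbers were checked for pairing across transcripts by correlating the deviations of libraries from their transcript means. Not all of the 15 correlations were over 0.1, so equal numbers were not treated as pairs.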

Results

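SERPINA1 encodes α-1-antitrypsin, a serine protease inhibitor that the liver secretes into blood. Its messenger RNAs carry different 5′ untranslated regions (5′ UTRs) in front of the same coding sequence. RNA of 6 SERPINA1 transcript variants (1, 2, 3, 4, 8 and 9) was folded in vitro at 37 °C for 10 to 15 minutes and probed by SHAPE-MaP. In this assay the reagent 1M7 modifies the ribose 2′-hydroxyl of flexible nucleotides, and reverse transcriptase records each modification as a mutation in the sequencing reads. High normalized reactivity marks a flexible nucleotide, and low reactivity marks a constrained one, as in a base pair. The question addressed was whether the 5′ UTRs, and the sequence that the transcripts share, folded differently from one transcript to the next.

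Each transcript was measured in 2 libraries, 12 in all, and each library held an untreated, a 1M7-treated and a denatured channel. Median depth per nucleotide was 26655 to 114090 reads in the untreated channel, 20224 to 115222 in the treated channel and 22558 to 131625 in the denatured channel. At this depth the median standard error of the normalized reactivity was 0.0523 to 0.160 per library. The untreated background had a median mutation rate of 0.134% to 0.301%, against 0.300% to 0.555% after 1M7. Replicate 1 of variants 1, 2 and 3 stood apart with untreated rates of 0.260% to 0.301%, and the other 9 libraries lay between 0.134% and 0.185%. They stood apart in the other channels too, so the difference is not one of the background alone. Their median rates were 0.544% to 0.555% after 1M7, against 0.300% to 0.376% in the other libraries. In the denatured channel they were 0.471% to 0.543%, against 0.2355% to 0.294%. The 2 libraries of each transcript differed by more than their standard errors, with a standard deviation of the scaled difference of 1.13 to 1.57, so each was counted as a separate replicate. Nothing in the labels says whether they came from separate RNA preparations, and the p-values measure only the spread between these samples, which may be technical.

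The transcripts were 1497 to 1811 nt long and shared the whole coding sequence of 1257 nt (418 codons and the stop codon) plus the 4 nt before it. The 5′ UTR was 261 nt long in variant 1, 554 nt in variant 2, 240 nt in variant 3, 277 nt in variant 4, 533 nt in variant 8 and 551 nt in variant 9. Variants 2, 3, 4, 8 and 9 began with the same 236 nt, called the leader here. Variants 2, 8 and 9 continued with a further 192 nt in common, called the middle segment. Variants 1, 2, 8 and 9 shared 102 nt that ended 4 nt before the start codon, called the proximal segment. Variant 1 thus had the proximal segment without the leader, and variants 3 and 4 had the leader without the proximal segment. Positions are counted in nt from the first nucleotide of the measured transcript or, where so stated, of the coding sequence.

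The shared coding sequence held flexible and constrained stretches at similar places in the 6 transcripts, whose libraries correlated at a mean Spearman's rho of 0.845 over the shared nucleotides. The most reactive 25-nt window was coding nt 1122 to 1146 (codons 374 to 382), with a mean reactivity of 1.08 ± 0.0680 (SD, n = 6 transcripts). It lay inside the codons of the reactive centre loop, the exposed loop by which the inhibitor traps its target protease. The other 4 of the 5 most reactive windows were nt 1171 to 1195 (0.955 ± 0.0429), nt 536 to 560 (0.886 ± 0.0304), nt 485 to 509 (0.860 ± 0.0405) and nt 951 to 975 (0.821 ± 0.0192). The least reactive window was nt 74 to 98, directly after the codons of the signal peptide, at 0.146 ± 0.0234. It was followed by nt 400 to 424 (0.154 ± 0.0251), nt 253 to 277 (0.177 ± 0.0389), nt 47 to 71 in the last codons of the signal peptide (0.214 ± 0.0202) and nt 144 to 168 (0.220 ± 0.0386). The 25 nt from 1122 averaged 0.956 to 1.21 in the 12 libraries, and the 25 nt from 74 averaged 0.107 to 0.216. GC content was 56% to 72% in the 5 least reactive windows and 32% to 48% in the 5 most reactive ones.

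The codons of the reactive centre loop as a whole (coding nt 1102 to 1158) had a mean reactivity of 0.747 ± 0.0258 (SD, n = 6 transcripts). This was at percentile 95.5 of all 1201 coding windows of that length. The signal peptide, which directs the nascent protein to the endoplasmic reticulum (coding nt 1 to 72), had a mean reactivity of 0.420 ± 0.0245, at percentile 29.8 of 1186 windows. Neither region differed detectably between transcripts, with ranges of 0.0561 for the loop and 0.0492 for the signal peptide (exact permutation p = 0.609 and 0.310; both tests were added after the data were examined). The ranges depend on the settings: with median scaling they were 0.204 and 0.142 (exact permutation p = 0.157 and 0.0776). Without replicate 1 of variant 3 the loop range was 0.0984 (exact permutation p = 0.339), and without replicate 2 of variant 1 or of variant 2 that of the signal peptide was 0.0750 or 0.0808 (exact permutation p = 0.197 and 0.119). The percentiles describe these profiles and are not tests.

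**Figure D1:**
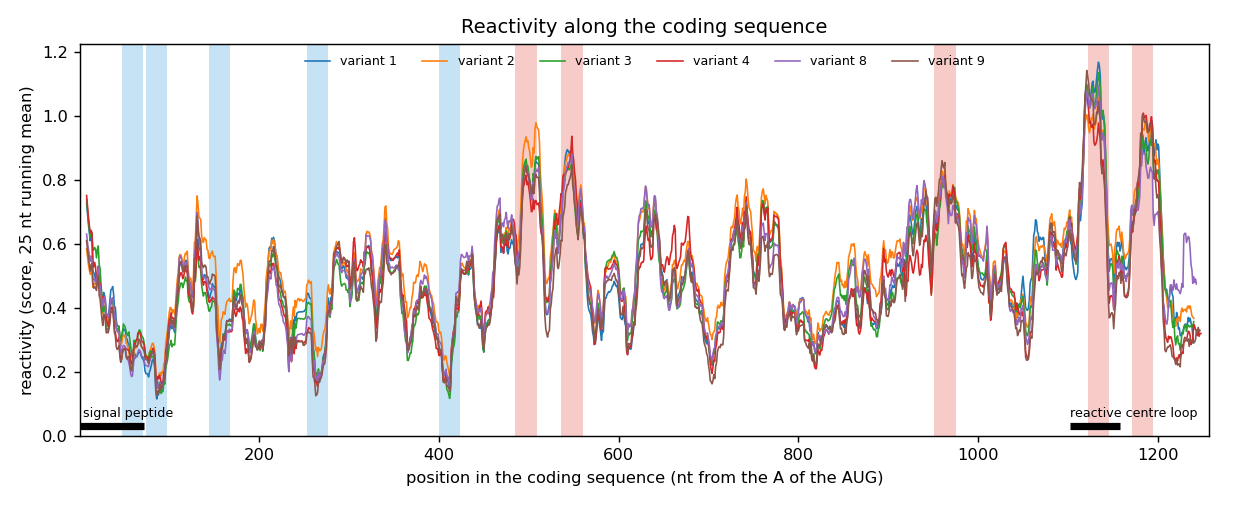
Reactivity along the coding sequence (running mean over 25 nt, y axis) against the position from the A of the start codon (nt, x axis), one line per transcript as the mean of its 2 libraries, with the 5 most and 5 least reactive windows shaded. The lines of the 6 transcripts rise and fall together, from 0.146 in the window at nt 74 to 1.08 in the window at nt 1122.

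Uridines were the most reactive base and cytidines the least. Mean reactivity was 0.718 ± 0.0253 at U, 0.600 ± 0.0338 at A, 0.413 ± 0.0174 at G and 0.294 ± 0.0407 at C (SD, n = 6 transcripts). The order U above A above G above C held in 12 of 12 libraries. The mean steps were 0.118 ± 0.0430 from A to U, 0.187 ± 0.0279 from G to A and 0.118 ± 0.0396 from C to G. These steps were not tested, since their order was read from the same means. The comparison fixed in advance, purines minus pyrimidines, came to −7.24e-05 (exact sign-flip permutation p = 1, adjusted p = 1), since it sets A and G, the middle ranks, against U and C, the highest and the lowest. Its sign turned under 3 other settings and without 6 single libraries, so no direction was detectable.

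Within codons, position 3 was the most reactive once base identity was taken out. After subtracting the mean of its base, reactivity averaged 0.0509 at position 3, −0.00919 at position 1 and −0.0418 at position 2 over 412 codons. Position 3 exceeded the mean of the other positions by 0.0764 (two-sided permutation test over 100000 resamples within codons, p = 0.00176, adjusted p = 0.00808 over 8 tests). Among the 9 libraries with the lower untreated rate the difference was 0.0749 (permutation p = 0.00203). Without the base adjustment it was 0.00111 (permutation p = 0.964), so the call rests on taking base identity out. As measured, position 2 was the highest, at 0.514, against 0.499 at position 3 and 0.481 at position 1. The permutation treats neighbouring codons of a single coding sequence as independent, so its p does not speak for replicates or transcripts.

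The first comparison between transcripts asked whether 2 libraries of one transcript had more similar profiles over the shared sequence than libraries of different transcripts. They hardly did. Over the 1247 shared nucleotides measured in every library, Spearman's rho averaged 0.851 in the 6 same-transcript pairs (0.812 to 0.905) and 0.845 in the 60 pairs of different transcripts (0.757 to 0.918). Only 2 of the 12 libraries had their highest correlation with their own partner. Replicate 1 of variant 1, whose median standard error was the lowest (0.0523, against 0.0773 to 0.160), was the best match of 9 of the other 11. The libraries with the higher untreated rate, which belong to 3 transcripts, correlated with each other at 0.904 on average (3 pairs). These are correlations across nucleotides, which are not independent, so the library was the unit of the test. Among all 10395 ways to pair the libraries, the exact one-sided permutation p was 0.094 (adjusted p = 0.150 over 8 tests; the smallest possible is 9.62e-05). With Pearson's r the mean was 0.872 and p = 0.0312. Within the 9 libraries of the lower untreated rate the means were 0.838 and 0.834 (exact permutation p = 0.366). Without replicate 2 of variant 1 or replicate 2 of variant 4 the same-transcript mean, 0.840 and 0.846, fell below that of the other pairs (p = 0.663 and 0.493), and without replicate 1 of variant 9 it was 0.859 (exact permutation p = 0.0109).

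**Figure D2:**
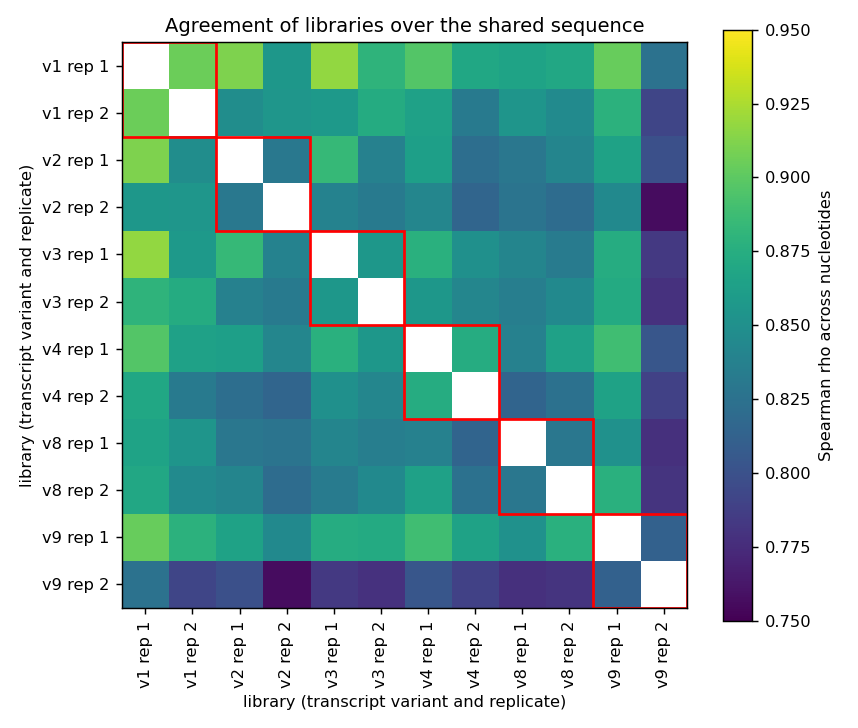
Spearman's rho of reactivity over the shared nucleotides for each pair of the 12 libraries (colour scale, no unit), with red squares around pairs of the same transcript. Same-transcript pairs average 0.851 and pairs of different transcripts 0.845.

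At single nucleotides of the shared sequence, no difference between the 6 transcripts was detectable. limma's moderated F test on log2(reactivity + 0.1) called 0 of 1247 nucleotides at an adjusted p under 0.05, and 98 had an unadjusted p under 0.05. Each of the 15 contrasts between 2 transcripts also gave 0. With the negative reactivities kept on the linear scale limma called 3, and with a variance trend it called 1. In simulated data of this size with 200 changed nucleotides, the same test recovered 13.1% of those changed by 1 on the log2 scale and 55.1% of those changed by 2, so changes of that size could have been missed. With no nucleotide called, the place of called nucleotides along the shared sequence could not be given.

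Upstream of the start codon, 5′ UTRs were slightly less reactive than the coding sequence in 5 of 6 transcripts. The median reactivity was 0.294 ± 0.0346 in the 5′ UTR and 0.317 ± 0.0355 in the coding sequence (SD, n = 6 transcripts). The difference of the medians averaged −0.0232 ± 0.0273, from −0.0486 in variant 8 to 0.0280 in variant 9. In variant 9 it was 0.00176 in replicate 1 and 0.0543 in replicate 2, the library with the highest share of negative reactivities (23.1%). The averaged difference did not pass the test (exact two-sided sign-flip permutation p = 0.125, adjusted p = 0.167 over 8 tests). With means in place of medians it was −0.0327 (exact permutation p = 0.03125, the smallest possible over 6 transcripts, which share sequence and are not fully independent). The 5′ UTRs held more G and C (57.9% to 62.9%) than the coding sequence (52.0%). With the means of A, C, G and U weighted equally the averaged difference was −0.0108 and did not pass. Among the libraries of the lower untreated rate it was −0.0226 (exact permutation p = 0.125). Against coding windows of the same length, the 5′ UTR median lay at percentile 31.4 ± 22.4.

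Between transcripts, the median reactivity of the 5′ UTR was highest in variant 2, at 0.359 ± 0.0332 (SD, n = 2 libraries), and lowest in variant 4, at 0.261 ± 0.0204. Variant 9 had 0.298 ± 0.00778, variant 1 0.287 ± 0.0173, variant 3 0.283 ± 0.0176 and variant 8 0.273 ± 0.0101. Variant 2 also had the highest coding median (0.378), and its 5′ UTR median minus its coding median was −0.0189 ± 0.00504. That lay between −0.0486 in variant 8 and 0.0280 in variant 9, so its 5′ UTR was not high against its own coding sequence. The range of the 5′ UTR median, 0.0983, had an exact permutation p of 0.0272 over all pairings, which did not hold after adjustment over 8 tests (adjusted p = 0.0726). The median of the coding sequence, added after the data were examined, also differed between transcripts, from 0.270 ± 0.0449 in variant 9 to 0.378 ± 0.0383 in variant 2 (exact permutation p = 0.0157, adjusted p = 0.0374 over 5 added tests). That difference had p of 0.0549 to 0.151 without any single library except replicate 1 of variant 2 or 9 (0.0157 and 0.00510), and p = 0.165 among the libraries of the lower untreated rate (exact permutation tests). Among the 9 libraries of the lower untreated rate the range of the 5′ UTR median was 0.122 (exact permutation p = 0.0897). Without replicate 2 of variant 2 the range was 0.0748, without replicate 2 of variant 4 it was 0.0864, and without either library of variant 8 or 9 it stayed at 0.0983, with exact permutation p of 0.0546 to 0.0797 in these 6 cases.

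**Figure D3:**
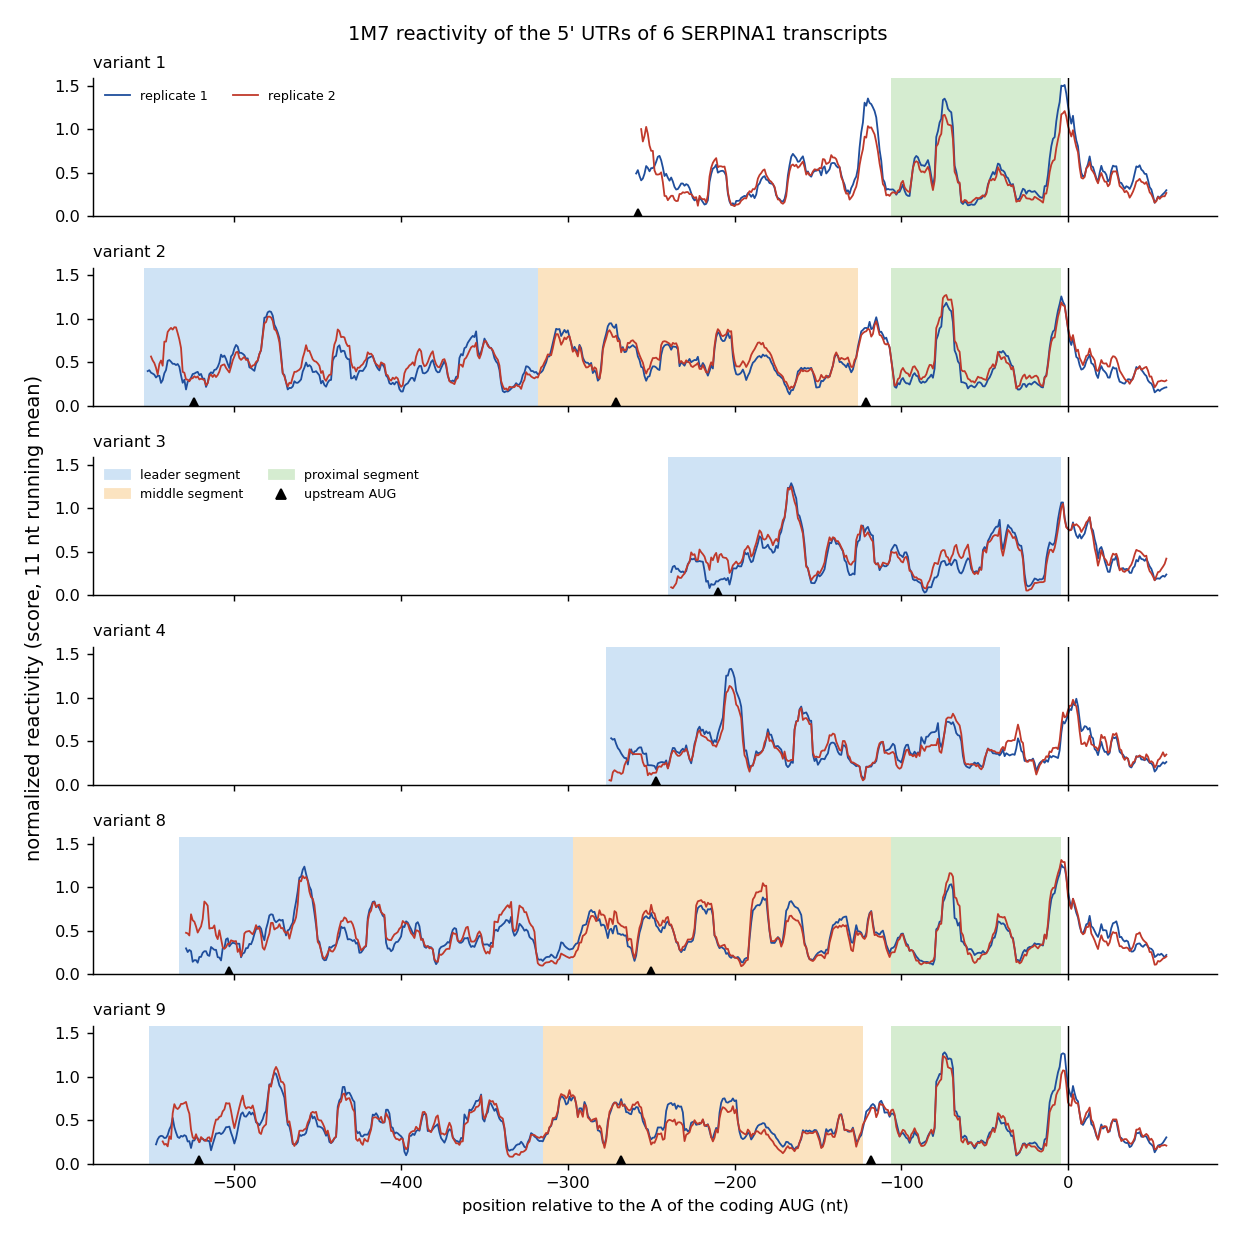
Reactivity along the 5′ UTR of each transcript (running mean over 11 nt, y axis) against the position relative to the A of the start codon (nt, x axis), 1 panel per transcript and 1 line per library, with the leader, middle and proximal segments shaded and upstream AUGs marked by triangles. Both libraries of a transcript follow the same peaks, and the mean reactivity within 10 nt of the AUG at leader nt 31 is below that of the rest of the 5′ UTR in the 5 transcripts that hold it.

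Around the start codon, mean reactivity from 20 nt upstream to 20 nt downstream of its A was 0.612 ± 0.0570 (SD, n = 6 transcripts). This was at percentile 77.1 ± 8.64 of the coding windows of that length. Variant 8 had the highest value, 0.675 ± 0.00626 (SD, n = 2 libraries), and variant 4 the lowest, 0.523 ± 0.00235. Variant 1 had 0.668 ± 0.0869, variant 3 0.622 ± 0.0202, variant 2 0.610 ± 0.0149 and variant 9 0.577 ± 0.0444. The window holds the same bases in variants 1, 2, 8 and 9, where the values ran from 0.577 to 0.675. Variants 3 and 4 lack the proximal segment and have other bases upstream of the start codon. The range over all transcripts and its tests therefore compare windows of different sequence. The range of 0.151 did not pass the exact permutation test (p = 0.0605, adjusted p = 0.121 over 8 tests), nor among the libraries of the lower untreated rate (p = 0.0540). Replicates of variant 1 lay far apart, and the p was 0.0122 without its replicate 1 and 0.00154 without its replicate 2, when the range was 0.206 (exact permutation tests). Within 10 nt of the A the range was 0.300 (exact permutation p = 0.0423), and within 40 nt it did not pass (p = 0.163).

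The stretches around upstream AUGs, where short open reading frames begin before the coding sequence, lay below the rest of the 5′ UTR in reactivity at 1 AUG and above it at the others. The AUG at leader nt 31 opens a reading frame of 13 codons in variants 2, 3, 4, 8 and 9. Reactivity within 10 nt of it was below that of the rest of the 5′ UTR in 10 of 10 libraries, by −0.228 ± 0.00310 in variant 2, −0.253 ± 0.132 in variant 3, −0.229 ± 0.0352 in variant 4, −0.181 ± 0.0534 in variant 8 and −0.176 ± 0.0932 in variant 9 (SD, n = 2 libraries each). The 3 nt of this AUG were close to the rest of the 5′ UTR in 4 of these transcripts, with 0.520 ± 0.116 against 0.497 in variant 2, 0.494 ± 0.246 against 0.485 in variant 3, 0.480 ± 0.182 against 0.471 in variant 8 and 0.427 ± 0.00938 against 0.449 in variant 9. In variant 4 they had 0.294 ± 0.0470 against 0.436. The AUG at nt 284 of variants 2, 8 and 9, with a frame of 30 codons, lay in a flexible stretch, with differences of 0.282 ± 0.0393, 0.138 ± 0.0364 and 0.209 ± 0.0167 within 10 nt of it. Its own 3 nt had 0.575 ± 0.00259 in variant 2, 0.545 ± 0.0544 in variant 8 and, below the rest, 0.437 ± 0.0945 in variant 9. The AUG at nt 434 of variants 2 and 9, with frames of 37 and 36 codons that end before the coding sequence, was also above the rest, by 0.316 ± 0.0565 and 0.119 ± 0.00393 within 10 nt of it, and its 3 nt had 1.21 ± 0.0299 and 0.855 ± 0.289. Variant 1 begins with the bases that variants 2 and 9 hold from nt 431, so its AUG at nt 4 is the same one. There it is in frame with the coding sequence and followed by a stop after 21 codons, with a difference of 0.264 ± 0.303. Averaged per transcript over its upstream AUGs the difference was −0.0108 ± 0.202 (exact two-sided sign-flip permutation p = 0.9375, adjusted p = 1, over 6 transcripts), so no common direction was detectable. Its sign turned with windows of 5 nt on each side (0.0189), among the libraries of the lower untreated rate (0.0368) and without replicate 1 of variant 1 (0.0249) or of variant 3 (0.00480). The separate AUG windows were not tested one by one.

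The next comparison asked whether the same 5′ UTR bases had the same profile in different transcripts. Over 16 shared stretches of at least 20 nt, the mean profiles of 2 transcripts correlated with a median Pearson's r of 0.895 (0.804 to 0.961). Replicates of one transcript correlated over the same nucleotides with a median of 0.919 (0.713 to 0.971), single libraries against single libraries. Single libraries of different transcripts had a median of 0.843 (0.787 to 0.943). The proximal segment gave both ends of the range between transcripts. Variants 2 and 9 had r = 0.961 (Spearman's rho 0.901) over 100 nt, whereas variants 1 and 8 had r = 0.804 (rho 0.633) over 104 nt, where their replicates correlated at 0.971 and 0.935. These correlations are across nucleotides, which are not independent replicates, and carry no test.

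Tests per nucleotide were then added to these segments, after the correlations had been seen. In the proximal segment variant 8 departed from the other transcripts that hold it. limma called 18 of 102 nucleotides at an adjusted p under 0.05, and 34 had an unadjusted p under 0.05. The contrasts of the same fit, each adjusted on its own, gave 18 nucleotides between variants 1 and 8, 18 between variants 8 and 9 and 9 between variants 2 and 8, against 4 between variants 2 and 9, 3 between variants 1 and 2 and 0 between variants 1 and 9. Variant 8 was the lowest at 9 of the 18, where its mean reactivity was 0.211 ± 0.0178, against 1.08 ± 0.10 in variant 1, 0.773 ± 0.0565 in variant 2 and 0.738 ± 0.0444 in variant 9 (SD, n = 2 libraries each). It was the highest at 6, with 0.558 ± 0.107 against 0.230 ± 0.00175, 0.398 ± 0.00112 and 0.258 ± 0.0320. Some of these 6 were near ties, as at nt 22, with 0.217 in variant 8 and 0.212 in variant 2. All 9 nucleotides called between variants 2 and 8 were higher in variant 2. Variant 8 was higher at 7 of the 18 called against variant 1 and at 10 of the 18 called against variant 9. At nt 28 of the segment, named after its values were seen, variant 8 had 0.0193 ± 0.0273 and the others 0.573 to 0.698 (limma, adjusted p = 0.0128). Averaged over the segment the transcripts lay close together, from 0.437 ± 0.0174 in variant 9 to 0.475 ± 0.0365 in variant 2. Other settings moved the counts between 2 transcripts. Variants 2 and 8 gave 1 with median scaling and 2 with the untreated rate class as a block. Variants 1 and 8 gave 19 and 14 there, variants 8 and 9 gave 19 and 16, and variants 2 and 9 gave 0 in both. Variants 1 and 9 gave 6 with negative reactivities kept.

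The count of 18 rested on most of the 8 libraries. limma called 0 without replicate 1 of variant 1 (27 unadjusted) or without its replicate 2 (23 unadjusted), 7 without replicate 2 of variant 2, 4 and 2 without replicates 1 and 2 of variant 9, and 14 or 15 without one of the other libraries. It called 0 among the 6 libraries of the lower untreated rate (26 unadjusted) and 3 with the untreated rate class as a block. The contrasts with variant 8 moved likewise. Against variant 1 the count was 3 and 2 without replicates 1 and 2 of variant 1 and 14 to 18 otherwise. Against variant 9 it was 7 without replicate 2 of variant 8, 0 without replicate 2 of variant 9 and 14 to 17 otherwise. Against variant 2 it was 1 and 0 without replicates 1 and 2 of variant 2, 2 without either library of variant 1, 4 without either of variant 9 and 9 without either of variant 8. Among the libraries of the lower untreated rate each of these 3 counts was 0. As a whole profile the segment differed more firmly: the spread between transcripts was 2.80 times the spread within them (exact permutation p = 0.00952, the smallest possible over the pairings; adjusted p = 0.0381 over 4 added tests). It was 2.39 times among the libraries of the lower rate, where another pairing gave a slightly higher ratio. It was 2.25 to 2.95 times when single libraries were left out. In the leader limma called 0 of 225 nucleotides over the transcripts together (24 unadjusted). Contrasts of that fit gave 2 nucleotides between variants 2 and 4, 1 between variants 3 and 8 and 1 between variants 3 and 9, and 0 in the others. With the untreated rate class as a block each of these was 0, and with negative reactivities kept variants 3 and 9 gave 7. In the middle segment it called 0 of 192 (54 unadjusted), with 5 between variants 2 and 8 and 1 between variants 2 and 9, each higher in variant 2, and 0 between variants 8 and 9. With negative reactivities kept it called 25 in the middle segment. Its contrasts then gave 28 between variants 2 and 8 and 14 between variants 8 and 9, and with pseudocount 0.5 they gave 28 and 4. Between variants 2 and 8 the count was 0 with the untreated rate class as a block and with pseudocount 0.05.

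**Figure D4:**
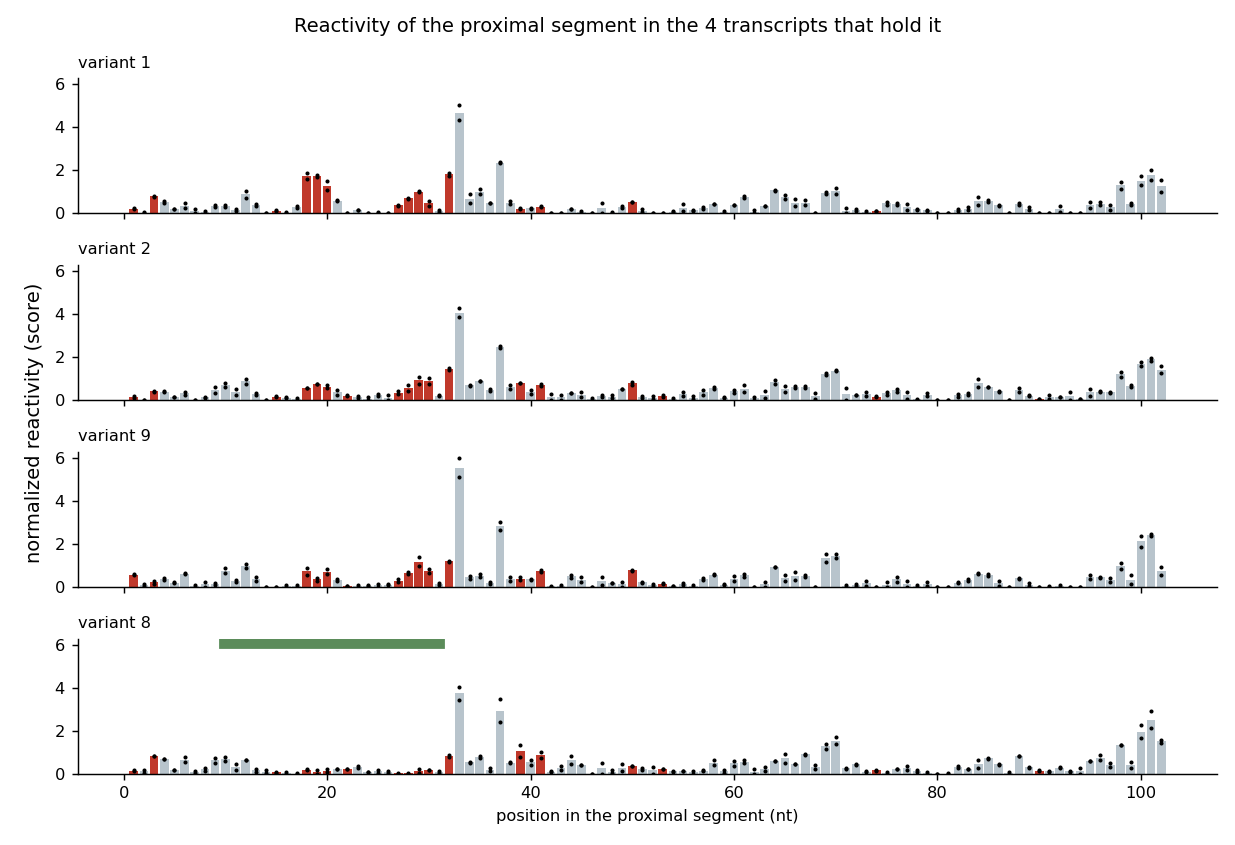
Reactivity (y axis) at the nucleotides of the proximal segment (nt of the segment, x axis) in the 4 transcripts that hold it, with bars at the mean of 2 libraries, dots at each library and the 18 called nucleotides in red. The green bar marks nt 10 to 31, the downstream arm of a helix in the folding model of variant 8, which has the lowest bar at 7 of the 9 called nucleotides under it.

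The last comparison used the reactivities to direct folding models of each transcript. The mean pairing probability of the 5′ UTR was highest in the transcripts whose 5′ UTR is mostly leader, at 0.652 ± 0.00792 in variant 4 and 0.649 ± 0.00163 in variant 3 (SD, n = 2 libraries). It was 0.599 ± 0.00233 in variant 9, 0.587 ± 0.0118 in variant 2 and 0.587 ± 0.000354 in variant 8, and lowest in variant 1, which lacks the leader, at 0.544 ± 0.00898. Sequence alone, without reactivities, already gave a range of 0.0796, from 0.583 in variant 1 to 0.662 in variant 4, against 0.108 with them. The exact permutation test fixed in advance (p = 0.00202, adjusted p = 0.00808 over 8 tests) therefore decides nothing, since both libraries of a transcript were folded from one sequence and the sequences differ. GC content of the 5′ UTR was 62.9% in variant 3, 62.1% in variant 4 and 57.9% to 59.5% in the others. The coding sequence lay between 0.513 and 0.537 in the 6 transcripts.

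Which bases were paired was less settled than how many. Of the 5′ UTR pairs with a probability of at least 0.5 in either library, 88.6% had it in both libraries of variant 3, 46.2% in variant 8, 30.5% in variant 2, 19.8% in variant 9, 18.3% in variant 4 and 6.33% in variant 1. Within 20 nt of the start codon, mean pairing probability ran from 0.511 ± 0.0269 in variant 8 to 0.638 ± 0.00933 in variant 4. Measured reactivity followed the fold predicted from sequence alone in part: it averaged 0.389 at nucleotides predicted as paired and 0.658 at those predicted as unpaired. The area under the curve that separates these classes was 0.656 on average over the libraries (0.622 to 0.689).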

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

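The tests of transcript differences in derived values, the fits to the proximal segment and their alternatives, the untreated-rate class, the spread ratios and the agreement within that class were chosen only after the results they bear on had been seen.

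The difference between 5′ UTR and coding sequence varied over the 6 transcripts, though most leave-outs of 1 library ended the call. It ranged over 0.0766, from −0.0486 in variant 8 to 0.0280 in variant 9, and the test of the difference itself passed (exact permutation p = 0.0224, adjusted p = 0.0374 over 5 added tests). When single libraries were left out it passed only without replicate 1 of variant 9, with a range of 0.103 (exact permutation p = 0.0224), and not without any other (p from 0.0522 to 0.129). Without replicate 2 of variant 9 the range was 0.0504 (exact permutation p = 0.129), and among the libraries of the lower untreated rate p was 0.245.

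The difference between upstream AUG windows and the rest of the 5′ UTR was a second such case. Its range was 0.516, from −0.253 in variant 3 to 0.264 in variant 1 (exact permutation p = 0.0199, adjusted p = 0.0374), and the transcripts differ in which upstream AUGs they hold. It passed without either library of variant 1 or without replicate 2 of variant 3, but not without any 1 of the others (exact permutation p from 0.0648 to 0.0812). Among the libraries of the lower untreated rate the range was 0.707, from −0.229 in variant 4 to 0.478 in variant 1. That top value is replicate 2 of variant 1 alone, and the 2 libraries of variant 1 averaged 0.264 ± 0.303 (SD). The only upstream AUG of variant 1 lies at nt 4, so its window reaches the first nucleotide of the transcript. Without transcript ends it had no value.

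The untreated channel, which the comparisons of reactivity use only as background, held a high mutation rate at 2 nucleotides, whose source (template, alignment or reverse transcription) was not tested and cannot be separated without reads. At coding nt 114, in codon 38, the untreated mutation rate averaged 6.29% ± 0.923 (SD, n = 12 libraries), 34.0 times the library median, against 3.99% ± 0.716 after 1M7 and 5.47% ± 0.829 in the denatured channel. At leader nt 19 it averaged 10.5% ± 1.77 in 10 libraries, against means of 13.7% after 1M7 and 11.3% in the denatured channel. The authors' processing left the reactivity out wherever the untreated rate was 5% or more, at leader nt 19 in these 10 libraries and at coding nt 114 in all but replicate 2 of variant 2, where the rate was 4.78%. Neither position entered the comparisons over nucleotides measured in every library.

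The first pattern weighed is the set of 18 nucleotides of the proximal segment that differed between transcripts. Among 100 pairings of the 8 libraries, the real one included, only the real one (1) gave 18 or more, and the highest other gave 9. The segment was tested after its correlations in the same libraries had been seen, and the re-pairings did not repeat that choice. Chance is therefore not excluded. The scaling of the libraries is argued against for the count over the transcripts together, which was 21 with median scaling. It was also 18 with reactivities as deposited, which tests little, since the main scaling used factors of only 0.953 to 1.03. Between variants 2 and 8 alone the count went from 9 to 10 as deposited and to 1 with median scaling. Between variants 2 and 9 it went from 4 to 0 under either setting, so these contrasts depend on the scaling. The libraries with the higher untreated mutation rate are argued against only weakly as the whole cause of the difference in profile. Over the whole segment the ratio of spread was 2.39 among the libraries of the lower class (exact permutation p = 0.0444), against 2.80 in all. Another pairing of those 6 libraries gave a slightly higher ratio (2.38907 against 2.38554), and only variants 8 and 9 keep both libraries there. At the 9 nucleotides where variant 8 was lowest, which were picked for that, its libraries had 0.223 and 0.198. Variant 9, also all of the lower class, had 0.707 and 0.769 there. Replicate 2 of variant 1 had 1.01 and replicate 2 of variant 2 had 0.813. Between variants 8 and 9, whose libraries are all of the lower class, the higher libraries cannot shift the difference itself. There were 16 called with the class as a block and 0 without the higher libraries, and these counts move only with the estimate of the spread. They therefore do not test the class as a cause, and its part in the number of nucleotides called over all transcripts stays open. A different fold of variant 8 is the biological explanation that the design offers, and it may account for the pattern only as a hypothesis.

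The second pattern is that libraries of one transcript were hardly more alike over the shared sequence than libraries of different transcripts. If the libraries with the higher untreated mutation rate masked a transcript effect, agreement within transcripts should have stood out once they were removed. Among the lower class it did not, with means of 0.838 in 3 pairs and 0.834 in 33 pairs (exact permutation p = 0.366), but 3 pairs with an SD of 0.0317 are too few to decide, so masking by these libraries stays open. A shared sequence that folds wholly alike behind every 5′ UTR is not excluded either: the spread between transcripts was 1.14 times the spread within them (exact permutation p = 0.0343, adjusted p = 0.0458), which goes against it, but 1.08 times among the lower class (exact permutation p = 0.341), and without most single libraries the ratio did not pass.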

How the results depend on the processing

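The fits restricted to the lower untreated-rate class or blocked by it, the fits to 5′ UTR segments, the spread ratios, the place at unadjusted p and the alternatives of the transcript differences in derived values were chosen after the data were seen. Passing means an unadjusted p under 0.05 for a test of one value and an adjusted one for counts of nucleotides. Of 455 alternative values of the comparisons, 350 kept direction and side of the threshold, 69 lost a call or part of a count, 20 gained, 1 moved and 15 changed sign; of 377 values of named windows 367 stayed within the replicate spread and 10 moved. The cause of a change was not tested, except where fewer libraries entered.

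With Pearson's r the agreement within transcripts passed (0.872), as did 5′ UTR minus coding sequence with means (−0.0327) and the start codon window at 10 nt (0.300). With the means of A, C, G and U weighted equally, 5′ UTR minus coding sequence was −0.0108 and did not pass. The 5′ UTR range passed only unadjusted (exact permutation p = 0.0272, adjusted p = 0.0726). Among libraries of the lower class, which are fewer, it no longer did (0.122), nor did the transcript differences in 5′ UTR minus coding sequence (0.0766) and coding median (0.135), the spread ratios of the shared sequence (1.08) and leader (1.26) and the proximal count (0), and the upstream AUG difference turned positive (0.0368), as with 5-nt windows (0.0189). Purines minus pyrimidines turned positive with median scaling (0.000413), negatives kept (0.00814) and the depth minimum (0.000128). Median scaling, which nearly equalises the coding median by construction, left its range at 0.00115. Position 3 lost its call with base identity kept (0.00111). With negatives kept limma called 3 shared, 1 leader and 25 middle nucleotides, with a variance trend 1, 1 and 5, and with pseudocount 0.5 1 leader and 4 middle nucleotides. The proximal count was 3 with the class as a block and 0 at an adjusted p under 0.01 (34 at unadjusted p under 0.05). Folding by sequence alone gave a range of 0.0796. The share of nucleotides at unadjusted p under 0.05 in the first 200 nt passed with the depth minimum (34.4%) and without transcript ends (34.0%), and in the first 100 nt (22.4%).

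Equal replicate numbers deviated together only among variants 1, 2 and 3 (3 correlations, 0.124 to 0.239), whose replicate 1 libraries form the higher untreated-rate class, so shared handling of those stays open; the other correlations of the 15 ran from −0.0879 to 0.0611, and the numbers were not treated as pairs. With the replicate block the start codon range, 0.151, passed (exact permutation p = 0.0252), the proximal count was 10 and the shared count 0 (104 at unadjusted p under 0.05). Contrasts between 2 transcripts were also lost with it. The count was 0 between variants 1 and 2 and variants 2 and 9 in the proximal segment, and between variant 2 and variants 8 and 9 in the middle segment. In the leader it was 0 between variants 2 and 4, 3 and 8, and 3 and 9. The block changed no other call among the results it was fitted to.

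Leaving out single libraries, agreement within transcripts ran from 0.840 to 0.859, below the other pairs without replicate 2 of variant 1 or 4 and past the threshold without replicate 1 of variant 9. The 5′ UTR range ran from 0.0748 to 0.122, with unadjusted p over 0.05 without replicate 2 of variant 2 or 4 or any library of variants 8 and 9. The start codon range ran from 0.147 to 0.206, gaining a call without either library of variant 1. The upstream AUG difference ran from −0.0464 to 0.0249, positive without replicate 1 of variant 1 or 3. Purines minus pyrimidines ran from −0.00530 to 0.00515, positive in 6 of 12 cases. The share in the first 200 nt ran from 20.8% to 34.6%, passing without either library of variant 2. The transcript differences ran from 0.0504 to 0.103 (5′ UTR minus coding sequence, passing only without replicate 1 of variant 9), 0.376 to 0.730 (upstream AUG windows) and 0.0765 to 0.140 (coding median, passing only without replicate 1 of variant 2 or 9). The proximal count ran from 0 to 15, the spread ratio from 1.02 to 1.37 (shared) and 1.10 to 1.53 (leader). The lone library of a transcript was assumed to vary like the others. The place of called nucleotides had no value because none was called, and the AUG of variant 1 had none without transcript ends. Between 1 and 54 nucleotides per library were under the depth minimum.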

Other observations

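The place of shared nucleotides at unadjusted p under 0.05, the spread ratios and the energy cost of the helix were chosen only after related results had been seen.

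The folding model of variant 8 held a helix that the models of the other transcripts lacked. It joins nt 326 to 347, in the middle segment, to nt 437 to 458, which are nt 10 to 31 of the proximal segment, through 19 pairs of which 12 are G with C, and it ends 76 nt before the start codon. Its mean pair probability was 0.985 and 0.988 in the 2 libraries of variant 8 and 0 in all 4 libraries of variants 2 and 9, which hold both arms. Reactivity at the paired bases was low on both arms in variant 8, at 0.178 ± 0.00227 upstream and 0.173 ± 0.0118 downstream (SD, n = 2 libraries). The same bases had 0.483 ± 0.0120 and 0.438 ± 0.0722 in variant 2, and 0.423 ± 0.00533 and 0.413 ± 0.0301 in variant 9. The downstream arm, the only one that variant 1 holds, had 0.547 ± 0.0357 there. Of the 18 nucleotides that differed in the proximal segment, 9 lie in this arm, and variant 8 was the lowest at 7 of them. The model was directed by the same reactivities, so the probability and the low reactivity are not independent evidence, and the helix was picked for being specific to variant 8.

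A hypothesis is that the short sequence present in variants 2 and 9 but absent from variant 8, between the middle and proximal segments, may keep the arms from pairing. The tests by sequence alone did not settle it. In a test set before its result was seen, pairing of the segment with the sequence upstream of it in variant 8 was predicted to differ opposite to reactivity at most called nucleotides. It did so at 3 of the 18 nucleotides (16.7%), against 43 of all 102 in the segment (42.2%), so this prediction failed. By sequence alone, however, the helix had probability 0 in variant 8 as well as in variants 2 and 9, so that count does not bear on what keeps the arms apart. Forcing its 19 pairs cost 3.3 kcal/mol in variant 8, 1.6 in variant 2 and 3.9 in variant 9, so the lowest cost in the others minus that in variant 8 was −1.7 kcal/mol, which goes against a saving in variant 8. An earlier version of that test, with 1 more pair nested inside the helix, cost 4.6 kcal/mol in variant 8, 11.4 in variant 2 and 12.7 in variant 9, a saving of 6.8 kcal/mol, so the outcome depends on that pair. The thermodynamic model used here separates the bases poorly, as the area of 0.656 shows, and the helix stays a hypothesis.

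Shared nucleotides with small p-values lay near the 5′ end of the shared sequence more often than its length would give, without passing the test at the distance fixed in advance. Of the 98 shared nucleotides with an unadjusted p under 0.05, 31 (31.6%) lay in the first 200 nt, which hold 15.9% of the sequence (exact one-sided permutation over circular shifts, p = 0.0825). In the first 100 nt there were 22 (22.4%, against 7.93% of the sequence; exact permutation p = 0.0103), and in the first 400 nt 38 (38.8%, against 31.7%; exact permutation p = 0.262). In steps of 100 nt the first held the highest share of such nucleotides, 22%, and the next 9.09% (9 of 99), below the 14.6% (7 of 48) at the 3′ end, from nt 1201 of the shared sequence. Without replicate 1 or 2 of variant 2 the share in the first 200 nt was 32.3% and 33.0% (exact permutation p = 0.00159 and 0.0452). Without replicate 1 of variant 9 it fell to 20.8% (exact permutation p = 0.124), and without any 1 of the remaining libraries it did not pass either (p from 0.0650 to 0.152). These nucleotides passed no adjusted threshold, so the list holds many chance entries.

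The ratio of spread between and within transcripts was lowest in the sequence that all transcripts share and highest in the proximal segment. It was 1.14 over the shared sequence (exact permutation p = 0.0343, adjusted p = 0.0458), 1.32 in the leader (p = 0.0243, adjusted p = 0.0458), 2.5 in the middle segment (p = 0.0667, the smallest possible with 6 libraries) and 2.80 in the proximal segment (p = 0.00952, adjusted p = 0.0381). The difference between segments was not tested, and they were measured in different transcripts. The ratio of the shared sequence lost its call without any 1 library (exact permutation p from 0.0645 to 0.387) except replicate 1 of variant 9, without which it was 1.37 (p = 0.00394). The leader lost it without either library of variant 2 or 4, replicate 2 of variant 3 or replicate 2 of variant 9 (p from 0.0847 to 0.247).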
